A study of Homo sapiens with 36 samples.

How the data were processed

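HEK293 is an established human line derived from embryonic kidney. HaloTag is a protein tag made from a bacterial enzyme that binds its ligands covalently, and HyT36 is a hydrophobic HaloTag ligand, used here at 25 µM with DMSO as the vehicle. The series holds 36 samples: 12 bulk RNA libraries, 16 single-cell libraries and 8 guide libraries. The 12 bulk libraries were analysed, and the other 24 samples were not analysed here. The bulk libraries come from a pair of clones that the labels number 4 and 5, each with DMSO and with HyT36, and 3 libraries per group. Which protein carries the tag in each clone is not given in the sources used here. The protocols name exposures of 2 and 12 h, and which of them applies to the bulk cultures is not given in the sources used here.

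Per the labels' protocols, bulk cell pellets were frozen and sent to a sequencing service, where libraries were made from polyA-selected RNA with a NEBNext Ultra II kit. The authors deposited 1 table of raw counts, not normalized, with 36601 genes, 22344 guide features and 4 summary entries per library, per the file headers. GRCh38 and Cell Ranger 7 are named in the submitters' processing notes, with no role stated for the bulk libraries. The aligner, the annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart, and near-identical paralogs such as HSPA1A and HSPA1B may share reads. The file's columns were matched to samples by their names.

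The gene counts made up 82.4 to 83.9% of all deposited counts in a library. Unmapped reads made up 3.18 to 4.26%, multimapping reads 2.23 to 2.82%, reads without a feature 2.95 to 4.18%, ambiguous reads 6.75 to 7.15% and guide features 0.00831 to 0.0125%. The summary entries and the guide features were left out of library sizes and tests. Gene counts per library ranged from 22853946 to 28635511, so a gene at 1 CPM rested on more than 20 reads in each library. Of the gene IDs, 36366 matched a symbol table, and 14 symbols that the table of the authors held as numbers were resolved by ID. Coordinates are those of RefSeq on GRCh38.p14, matched by symbol.

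Counts were tested with edgeR 4.0.16 under R 4.3.3. Genes were filtered with filterByExpr by group, which left 14892, and libraries were scaled by TMM. One model with a mean for each of the 4 groups was fitted over all 12 libraries, so that all groups shared an estimate of the spread, with robust quasi-likelihood dispersions and no covariate. The two-sided quasi-likelihood F-test was applied to the ligand response of clone 4, the ligand response of clone 5, the clone 5 response minus the clone 4 response, and clone 5 against clone 4 without ligand. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Fitted log2 fold changes use a prior count of 0.125. Each standard error is the size of the log2 fold change divided by the square root of F, which is an approximation. CPM values are TMM-scaled and are given as mean ± SD over the 3 libraries of a group.

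Before the data were examined, 30 gene lists were fixed for stress responses, metabolism, cell cycle, RNA quality and other cell types. The 29 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera was also run with a correlation estimated per list, and fry was run as a self-contained test. Genes named in the text were chosen by a rule fixed at the same time. For each ligand response and for the clone comparison it takes the 10 largest rises and the 10 largest falls among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups. For the difference of responses it takes 5 each way without the non-overlap condition. To these it adds up to 4 members with the smallest p of each list described, and 19 stress genes named in advance. Some genes that the rule names are not reported here. Further genes, among them the genes named by guides and members of lists given as examples, were chosen after their values were seen.

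For a gene with 1 to 3 reads in a group the ratio of reads is given with an exact 95% binomial interval, and for a gene with 0 reads a bound computed from a floor of 3 reads over the group. These intervals and floors cover counting error only. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicate libraries of a group were compared with a chi-square test of their counts. The chi-square per degree of freedom lay between 1.93 and 8.43, so no library pair looked like 1 library deposited 2 times.

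The code was tested on simulated counts drawn from the means and library sizes of these samples. In a simulated clone 4 ligand response over 14322 genes, 52.1% of the genes changed 1.25-fold were recovered, 66.7% at 1.5-fold, 86.0% at 2-fold and 96.0% at 4-fold, and 10 false calls made up 6.33% of all calls. In a simulated clone 5 ligand response, a list of 30 genes changed 1.3-fold was called with a camera adjusted p of 4.2e-61, and 0 of the other 29 lists were called. Simulated genes were independent, so that test says nothing about inter-gene correlation.

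Other fits, chosen at the same time, were DESeq2 1.42.0, limma-voom, size factors in place of TMM, no filter on low counts, a filter of 1 CPM in at least 3 libraries, a test against a fold of 1.2, the replicate number as a block, each clone fitted alone, the libraries without ligand alone, and each of the 12 libraries left out in turn. A further 4 were added after transcripts of epithelial marker genes were seen in 6 libraries: a model term for those libraries, the removal of genes higher in them, and fits of only those or only the other libraries. Marker lists of 20 breast luminal and 20 liver genes were also written then. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.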

Results

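The study asked which stress responses follow when an endogenous protein fused to HaloTag is bound by a hydrophobic ligand. Bulk RNA was sequenced in 12 libraries of HEK293 cells: clone 4 with DMSO, clone 4 with HyT36, clone 5 with DMSO and clone 5 with HyT36, with 3 libraries in each group. Gene counts were 23416253, 26013493 and 24282784 in clone 4 with DMSO, and 28635511, 27615857 and 26523002 in clone 4 with HyT36. They were 23486037, 26445021 and 26948771 in clone 5 with DMSO, and 23869381, 22853946 and 23226578 in clone 5 with HyT36. Cells without a tag were not part of the 12 libraries, so a response to the ligand itself and a response that needs the tag could not be separated.

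Guide reads marked the clones. A guide named for HDAC2, a histone deacetylase, had 2318 to 3504 reads in each clone 4 library and 2 to 18 in each clone 5 library. Its level in clone 4 was 112 ± 12.9 CPM with DMSO and 115 ± 10.1 CPM with HyT36 (SD, n = 3). A guide named for IGF1R, a growth factor receptor, had 2623 to 3806 reads in each clone 5 library and 5 to 13 in each clone 4 library. Its level was 130 ± 14.2 and 121 ± 10.5 CPM in clone 5 with DMSO and with HyT36 (SD, n = 3). Clone 5 libraries also held 107 to 140 reads each of a guide named for LRIG1, which is 3.85 for every 100 reads of the IGF1R guide there, against 0 in clone 4. Of the 22344 guide features, 68 had at least 1 read, and every guide other than these 3 had at most 4 reads in a library. HDAC2 lies on chromosome 6 at 113933028 to 113971148, IGF1R on chromosome 15 at 98648539 to 98964530 and LRIG1 on chromosome 3 at 66378797 to 66501121 (GRCh38.p14). By the edgeR quasi-likelihood test HDAC2 mRNA was higher in clone 5 than in clone 4 without ligand (log2 difference 0.53 ± 0.04, SE, Benjamini-Hochberg adjusted p = 1.4e-15). IGF1R mRNA was lower (-0.22 ± 0.05, edgeR adjusted p = 6.3e-04) and LRIG1 mRNA did not pass (-0.06 ± 0.12, adjusted p = 0.68). None of the 3 passed in either ligand response, with log2 fold changes of 0.02 and -0.00 for HDAC2, 0.12 and 0.14 for IGF1R, and 0.16 and 0.06 for LRIG1 in clones 4 and 5.

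Transcripts of epithelial marker genes split the libraries across the groups. The epithelial carcinoma line markers, a list that includes keratins and adhesion genes, summed to 53.4 to 108 CPM in 6 libraries and to 3.11 to 4.34 CPM in the other 6. The former were clone 4 DMSO replicate 1, clone 4 HyT36 replicates 2 and 3, and all 3 of clone 5 with DMSO. The keratin gene KRT19 ranged from 33.0 to 70.5 CPM in them and from 0.0420 to 0.231 CPM in the others. In clone 5 this split coincided with DMSO against HyT36, and in clone 4 it crossed both groups.

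**Figure D1:**
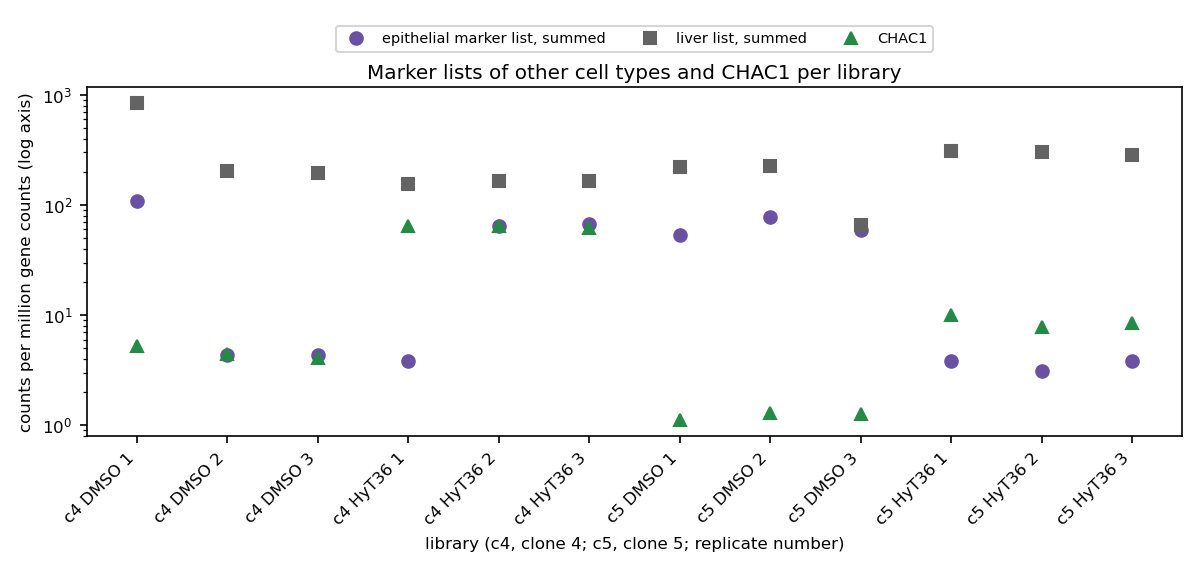
Summed CPM of the epithelial marker list, the same for a list of liver transcripts, and the level of CHAC1, as 1 point per library on a log axis. These CPM are not TMM-scaled. The 6 libraries at 53.4 to 108 CPM of the epithelial list are separate from the 6 at 3.11 to 4.34 CPM.

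In clone 4, HyT36 raised some genes of the integrated stress response, the ER stress response, the cytosolic heat shock response and sterol synthesis, and lowered some cytoskeletal and p53 target genes. As lists, with an estimated correlation the integrated stress response and sterol synthesis genes passed (camera adjusted p = 0.0019 each), and the ER stress (0.21), heat shock (0.083), cytoskeletal (0.21) and p53 (0.21) genes did not. CHAC1, a glutathione-degrading enzyme induced by ATF4, rose from 4.61 ± 0.524 to 65.2 ± 2.04 CPM, 14.1-fold (SD, n = 3). DDIT4, an inhibitor of mTORC1 signalling, rose from 4.86 ± 1.83 to 58.5 ± 3.18 CPM, 12.1-fold. ASNS, which makes asparagine, rose 4.87-fold and DDIT3, the stress transcription factor CHOP, 3.29-fold. Both were at low levels with DMSO. ASNS had 0.677, 0.432 and 0.957 CPM in the 3 libraries and DDIT3 1.42 ± 0.500 CPM. HERPUD1, a membrane protein of ER-associated degradation, rose from 42.9 ± 1.12 to 89.3 ± 4.01 CPM. Of 14892 genes tested, 830 passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, of which 329 rose and 501 fell, and 19 changed by more than 2-fold, 10 up and 9 down. With DESeq2 48.7% of the called genes rose, against 39.6% here.

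Among the genes of clone 4 with a mean log2 CPM of at least 1 and no overlap between the groups, the largest log2 fold change was that of CHAC1 at 3.82 ± 0.09 (SE; edgeR adjusted p = 1.1e-30; chromosome 15, 40953471 to 40956512). That of DDIT4 was 3.59 ± 0.18 (adjusted p = 3.4e-06; chromosome 10, 72273924 to 72276036). ASNS rose by 2.28 ± 0.27, DDIT3 by 1.72 ± 0.22 and HERPUD1 by 1.06 ± 0.05 (edgeR adjusted p = 1.1e-07, 1.1e-06 and 7.6e-19). The transcription factor gene CEBPB rose by 1.37 ± 0.24, the glucocorticoid-responsive TSC22D3 by 1.04 ± 0.08, the ER co-chaperone gene DNAJB9 by 0.83 ± 0.08, the homeobox gene IRX2 by 0.81 ± 0.20 and the transcriptional repressor gene BCL6 by 0.80 ± 0.17 (edgeR adjusted p = 0.012, 1.6e-12, 2.3e-09, 0.010 and 0.0018). XBP1, a transcription factor of the ER stress response on chromosome 22 (28794560 to 28800569), rose from 133 ± 0.440 to 199 ± 3.06 CPM (log2 fold change 0.58 ± 0.04, edgeR adjusted p = 2.1e-14). Within the same limits the falls were led by the phosphatase gene DUSP5 (-0.94 ± 0.24), KLF10 (-0.93 ± 0.08), the kinase gene NUAK2 (-0.91 ± 0.17), the homeobox gene NKX2-2 (-0.88 ± 0.18) and the p53 target and cell cycle inhibitor gene CDKN1A (-0.88 ± 0.15). They continued with the AP-1 gene JUNB (-0.86 ± 0.11), the arrestin family gene ARRDC4 (-0.85 ± 0.11), the transporter gene SLC16A6 (-0.82 ± 0.13), the matricellular gene CCN2 (-0.79 ± 0.09) and the hyaluronan synthase gene HAS3 (-0.74 ± 0.17).

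Of 44 tested PERK and ATF4 targets, 23 rose and 1 fell in clone 4 (31 and 1 adjusted over the list alone). Beside CHAC1, DDIT4, ASNS and DDIT3, the rises included ATF3 (0.77 ± 0.08), the secreted glycoprotein gene STC2 (0.77 ± 0.05), the amino acid transporter gene SLC38A2 (0.58 ± 0.05) and ATF4 itself (0.17 ± 0.05, edgeR adjusted p = 0.044). The fall was GDF15 (-1.66), a stress-induced cytokine named after its value was seen, and the pseudokinase gene TRIB3 did not pass (0.13 ± 0.06, edgeR adjusted p = 0.20). Of 29 SREBP2 targets 11 rose and the other 18 did not pass (16 rises adjusted over the list alone). Among them were INSIG1 (0.60 ± 0.04) and MSMO1 (0.52 ± 0.05), genes of sterol synthesis or its control. By limma camera both lists were higher (adjusted p = 9.4e-26 and 2.2e-13), and both calls held with an estimated correlation (adjusted p = 0.0019 each). Of 31 HSF1 targets 10 rose and the other 21 did not pass (13 rises and 1 fall adjusted over the list alone). The rises were led by the chaperone genes DNAJB1 (0.76 ± 0.04), HSPA1B (0.81 ± 0.06), HSPA1A (0.64 ± 0.05) and HSPA8 (0.35 ± 0.03). HSPA1A and HSPA1B are near-identical, so the split between them is uncertain, and HSPB1 (0.06 ± 0.08) did not pass. As a list the HSF1 targets were higher (camera adjusted p = 6.5e-09, and adjusted p = 0.083 with an estimated correlation). Of 37 ATF6 and XBP1 targets 4 rose (4 adjusted over the list alone): HERPUD1, XBP1, DNAJB9 and, at 0.19 ± 0.03, the main ER chaperone gene HSPA5. SDF2L1 (-0.00 ± 0.06) was among the other 33, and the list was higher (camera adjusted p = 0.0011, and adjusted p = 0.21 with an estimated correlation).

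The p53 targets were lower in clone 4 (camera adjusted p = 1.9e-06, and adjusted p = 0.21 with an estimated correlation). Of 24 tested, 5 fell and 1, SESN2, rose (11 and 2 adjusted over the list alone), with falls of CDKN1A, GADD45A (-0.59 ± 0.10), BTG2 (-0.57 ± 0.08) and AEN (-0.27 ± 0.04). Lower too were the cytoskeleton and SRF targets (camera adjusted p = 1.0e-04, and adjusted p = 0.21 with an estimated correlation), where 6 of 25 fell and 1 rose (7 and 1 adjusted over the list alone). The falls included CCN1 (-0.62 ± 0.05), CCN2, FHL2 (-0.38 ± 0.07) and SRF itself (-0.31 ± 0.04). Immediate early genes, 9 of which fell and 3 rose among 30 (10 and 5 adjusted over the list alone), were lower as a list (camera adjusted p = 0.0039, and adjusted p = 0.15 with an estimated correlation). Proteasome subunits were higher by camera (adjusted p = 3.1e-04, and adjusted p = 0.69 with an estimated correlation) at a median log2 fold change of 0.05. Of these 38 genes 0 passed by edgeR, DESeq2 or limma-voom (0 adjusted over the list alone), and 5 had an unadjusted edgeR p under 0.05. The epithelial markers did not pass in clone 4 (camera adjusted p = 0.43), and of their 10 members 0 passed by edgeR, DESeq2 or limma-voom and 1 had an unadjusted edgeR p under 0.05. In only the 6 libraries with few epithelial transcripts, where clone 4 with HyT36 has 1 library that is assumed to vary like the other groups, the count of 830 genes was 287 and the calls of DUSP5, HAS3, IRX2, NKX2-2, NUAK2, ATF4 and, at an adjusted p of 0.14, the proteasome subunits were lost. In only the other 6, where clone 4 with DMSO has 1 library under the same assumption, those of BCL6 (edgeR adjusted p = 0.30), GADD45A (0.11), FHL2 (0.093), CEBPB (0.070) and, by camera, the ATF6 and XBP1 targets (0.061) were lost.

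The 830 genes of clone 4 fell to 545, 532 and 409 without HyT36 replicate 1, 2 and 3, and to 52 against a fold of 1.2, where calls of small change such as that of HSPA5 (edgeR adjusted p = 1.0) were lost. Without HyT36 replicate 3 CDKN1A, DUSP5, HAS3 and IRX2 did not pass (edgeR adjusted p = 0.056, 0.074, 0.090 and 0.14). DUSP5 (edgeR adjusted p = 0.056) and the proteasome subunits (camera, 0.20) did not pass without DMSO replicate 1. Nor did CEBPB without DMSO replicate 3 (0.051) or with the replicate block (0.13), or the immediate early genes without HyT36 replicate 1 (camera, 0.057). CDKN1A did not pass with each clone fitted alone (0.081), and IRX2 did not with limma-voom (0.074). ATF4 did not pass without any clone 4 library but DMSO replicate 2 (0.051 to 0.17) and without 3 of clone 5 (DMSO 3, 0.099; HyT36 2 and 3, 0.050 and 0.056).

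**Figure D2:**
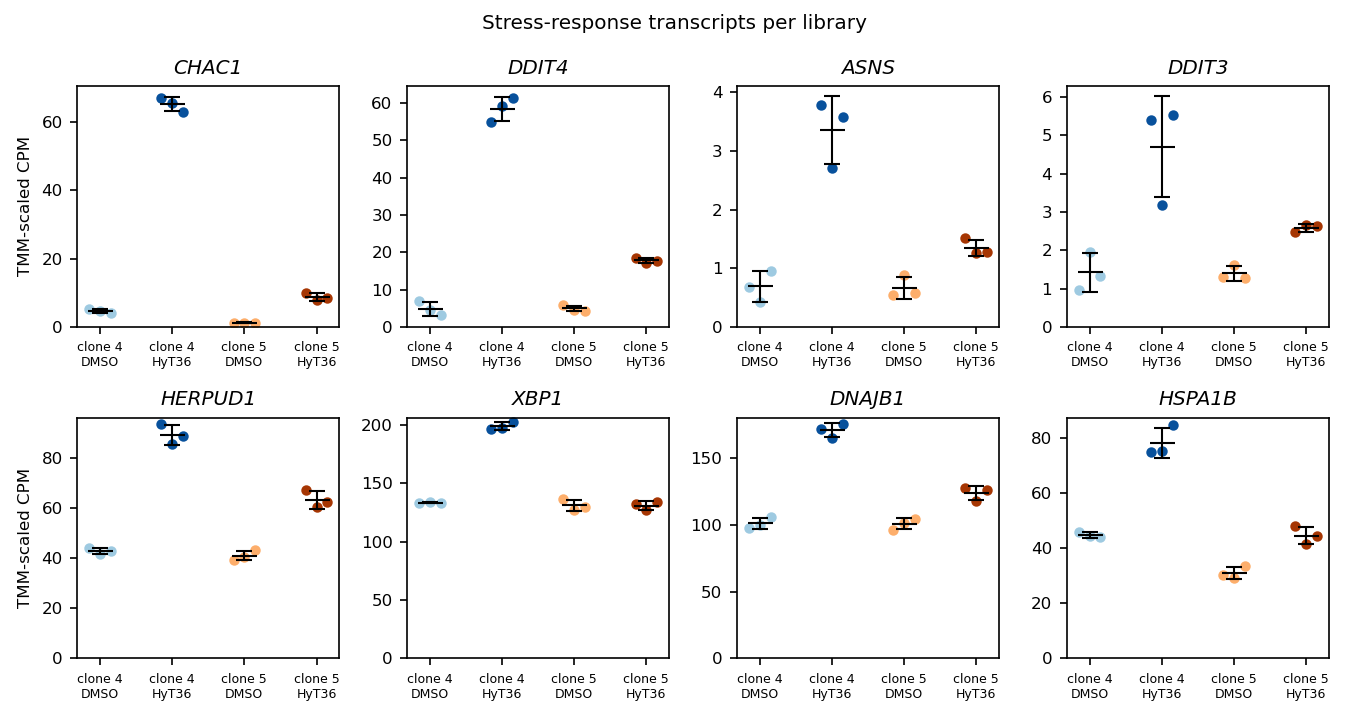
TMM-scaled CPM of 8 stress genes by clone and treatment, on axes from 0, with 1 point per library and the group mean ± SD as bars. CHAC1 lies at 4.61 and 65.2 CPM on average in clone 4 and at 1.19 and 8.70 CPM in clone 5.

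In clone 5, HyT36 also raised some integrated stress response, ER stress, heat shock and sterol synthesis genes and lowered some p53 targets. As lists, with an estimated correlation none of these passed (camera adjusted p = 0.077, 0.14, 0.14, 0.050 and 0.13 in that order). CHAC1 rose 7.26-fold, from 1.19 ± 0.0937 to 8.70 ± 1.12 CPM (SD, n = 3), DDIT4 3.63-fold, from 4.92 ± 0.793 to 17.8 ± 0.569 CPM, and HERPUD1 1.54-fold, from 41.0 ± 1.89 to 63.3 ± 3.50 CPM. TXNIP, an inhibitor of glucose uptake, fell 7.25-fold, from 25.1 ± 2.71 to 3.45 ± 0.145 CPM. Within the clone 4 groups TXNIP varied widely, at 17.2 ± 8.73 CPM with DMSO and 12.8 ± 5.17 CPM with HyT36 (SD). The edgeR quasi-likelihood test called 1219 of 14892 genes at a Benjamini-Hochberg adjusted p under 0.05, 499 higher and 720 lower, and 50 changed by more than 2-fold, 15 up and 35 down. With DESeq2 50.9% of the called genes rose, against 40.9% here. Beside these counts, the epithelial transcripts were also higher in every clone 5 library with DMSO than in every one with HyT36. Of the 720 falls, 11 were among the 297 genes that were higher in the libraries of clone 4 with such transcripts. Those genes vary within the clone 4 groups, and the estimate of the spread is shared by all groups, which makes them hard to call. This number therefore does not measure how much such transcripts contribute to the falls.

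The log2 fold changes in clone 5 were 2.86 ± 0.13 for CHAC1 (SE; edgeR adjusted p = 1.8e-19), 1.86 ± 0.20 for DDIT4 (adjusted p = 4.4e-04), 1.00 ± 0.29 for ASNS (adjusted p = 0.024) and 0.88 ± 0.23 for DDIT3 (adjusted p = 0.012). With DMSO ASNS had 0.542, 0.883 and 0.583 CPM in the clone 5 libraries and DDIT3 1.40 ± 0.194 CPM (SD), both low levels. The neurogenic factor gene NEUROG2 rose by 0.81 ± 0.09 and BCL6 by 0.71 ± 0.17 (edgeR adjusted p = 3.8e-08 and 0.0052). Other large rises were of genes that clone 5 barely expressed. NSG1, a neuronal endosomal protein gene, rose by 2.69 ± 0.53, and DAB2 and GALNT13 rose by 1.57 ± 0.43 and 1.35 ± 0.41. PPP2R2B, a phosphatase subunit gene, had 19 reads with HyT36 against 3 (ratio 6.96, counting interval 2.05 to 36.7), and RUNX1T1, a transcriptional corepressor gene, 9 against 1 (ratio 9.89, 1.37 to 434). At a mean log2 CPM of at least 1 and with no overlap, among the falls after TXNIP (-2.86 ± 0.46, edgeR adjusted p = 0.0066), the adhesion gene NCAM2 went from 21 reads to 0, at least 6.37-fold lower, and the semaphorin gene SEMA3D from 22 reads to 3 (ratio of 6.67, 2.00 to 34.8). MAGI2-AS3, an antisense RNA whose reads are uncertain because the strand is not stated, went from 14 reads to 2 (ratio of 6.37, 1.46 to 57.7). Further falls were those of NIBAN1 (-2.14 ± 0.35), SH2D4A (-1.87 ± 0.33), the epithelial splicing factor gene ESRP1 (-1.84 ± 0.43), GATA3 (-1.83 ± 0.44), NELL1 (-1.77 ± 0.41) and LRATD2 (-1.52 ± 0.39). ESRP1 is on the epithelial marker list, and both ESRP1 and GATA3 varied widely within the clone 4 groups. In clone 4 GATA3 had 12.96 ± 6.3 CPM with DMSO and 14.26 ± 4.55 CPM with HyT36 (SD). ESRP1 had 2.81 ± 1.42 and 3.4 ± 1.27 CPM in the same groups. The epithelial transcripts coincided with DMSO in clone 5, so their part in these falls of ESRP1 and GATA3 cannot be separated from the ligand. CDKN1A fell by 0.96 on the log2 scale (edgeR adjusted p = 0.0061). XBP1 (-0.00 ± 0.04), TRIB3 (-0.15 ± 0.06), SDF2L1 (0.01 ± 0.05), BAG3 (-0.08 ± 0.07), HMOX1 (0.13 ± 0.12), SQSTM1 (0.12 ± 0.09) and HSPB1 (-0.00 ± 0.08) did not pass.

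PERK and ATF4 targets were higher in clone 5 (camera adjusted p = 8.0e-08, and adjusted p = 0.077 with an estimated correlation). Of the 44, 14 rose and 1 (TXNIP) fell (21 and 3 adjusted over the list alone), with ATF3 at 0.67 ± 0.08, STC2 at 0.39, and the amino acid transporter genes SLC3A2 at 0.33 ± 0.04 and SLC38A2 at 0.33 ± 0.05. SREBP2 targets were higher as well (camera adjusted p = 1.4e-05, and adjusted p = 0.050 with an estimated correlation), 9 of 29 rising and 1 (SC5D) falling (10 and 1 adjusted over the list alone). Among the rises were INSIG1 at 0.45 ± 0.04 and MSMO1 at 0.43 ± 0.05. Among 31 HSF1 targets, higher as a list (camera adjusted p = 3.4e-05, and adjusted p = 0.14 with an estimated correlation), 7 rose and 1 (DNAJB6) fell (11 and 1 adjusted over the list alone). The rises included HSPA1B at 0.52 ± 0.06, DNAJB4 at 0.49 ± 0.07, HSPA8 at 0.35 ± 0.03 and DNAJB1 at 0.30 ± 0.04. ATF6 and XBP1 targets, also higher (camera adjusted p = 3.2e-04, and adjusted p = 0.14 with an estimated correlation), had 5 rises and 1 fall (DNAJC3) among 37 (8 and 2 adjusted over the list alone). The rises were HERPUD1 (0.63 ± 0.05), DNAJB9 (0.67 ± 0.09), HYOU1 (0.15 ± 0.04), HSPA5 (0.14 ± 0.03) and PDIA4 (0.12). The p53 targets were lower (camera adjusted p = 4.9e-10, and adjusted p = 0.13 with an estimated correlation), and 11 of 24 fell while 13 did not pass (14 falls adjusted over the list alone). Examples are PHLDA3 at -0.95 ± 0.11, the death receptor genes FAS at -0.78 and TNFRSF10B at -0.32 ± 0.04, and TIGAR at -0.29 ± 0.05. Lower too were the immediate early genes (camera adjusted p = 4.3e-04, and adjusted p = 0.077 with an estimated correlation), with 9 falls and 2 rises among 30 (15 and 2 adjusted over the list alone). Among the falls were KLF10 at -0.76 ± 0.08, CCN2 at -0.54 ± 0.10 and FOSL1 at -0.50 ± 0.07.

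Camera called 8 further lists in clone 5, 7 of them higher. Nuclear lamina, pore and transport genes (adjusted p = 0.0064, and adjusted p = 0.33 with an estimated correlation) had 7 rises and 2 falls among 28 (10 and 3 adjusted over the list alone). Among them were NUP205 (0.26 ± 0.04) and IPO7 (0.19 ± 0.04) up and NUP62 (-0.21 ± 0.04) down. For the 38 respiratory chain subunits (camera adjusted p = 0.0054, and adjusted p = 0.54 with an estimated correlation) the call was the rise of NDUFS1 (1 adjusted over the list alone). For the 38 proteasome subunits (camera adjusted p = 0.0097, and adjusted p = 0.66 with an estimated correlation) 2 rose (1 adjusted over the list alone). The 72 ribosomal proteins (camera adjusted p = 0.0075, and adjusted p = 0.78 with an estimated correlation) had 1 call, a fall of RPS10, against the direction of the list. The 28 NRF2 targets (camera adjusted p = 0.0075, and adjusted p = 0.14 with an estimated correlation) had 1 rise and 1 fall, the same numbers adjusted over the list alone. Of 20 TGF-beta and matrix genes 2 rose, ID3 and the collagen gene COL1A2 (2 adjusted over the list alone), and of 9 fibroblast markers 2 rose, PDGFRA and COL1A2 (2 adjusted over the list alone). Camera gave these lists adjusted p = 0.014 and 0.021, and adjusted p = 0.31 and 0.17 with an estimated correlation. The 10 epithelial markers were lower at a median of -2.30 (camera adjusted p = 0.0054, and adjusted p = 0.54 with an estimated correlation), with 1 fall, ESRP1 (1 adjusted over the list alone).

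With a term for the libraries with epithelial transcripts the count of clone 5 was 776 genes. The term ended the calls of ASNS (edgeR adjusted p = 0.29), DDIT3 (0.51), CDKN1A (0.079), ESRP1 (0.27), DAB2 (0.059), GALNT13 (0.13), RUNX1T1 (0.068), MAGI2-AS3 (0.067), LRATD2 (0.091), HYOU1 (0.16), DNAJC3 (0.27), NDUFS1 (0.30), ID3 (0.46) and RPS10 (0.22). By camera it ended those of the nuclear (adjusted p = 0.16) and respiratory chain (0.93) lists, and turned the direction of the proteasome subunits (0.35), the ribosomal proteins (0.21) and the epithelial markers (0.042). The count of 1219 genes fell to 755 without DMSO replicate 1 and to 37 against a fold of 1.2. TXNIP did not pass with the replicate block (edgeR adjusted p = 0.092), and DAB2, PPP2R2B, NELL1, LRATD2, ESRP1, ASNS and DDIT3 did not with limma-voom (0.057, 0.057, 0.081, 0.056, 0.063, 0.068 and 0.077). Without DMSO replicate 1 the calls of ASNS (0.12), DDIT3 (0.061), HSPA5 (0.050), HYOU1 (0.070), GALNT13 (0.059), RUNX1T1 (0.18), MAGI2-AS3 (0.37), NELL1 (0.18) and LRATD2 (0.067) were lost. Without DMSO replicate 2 HSPA5 (0.052), DAB2 (0.19), GALNT13 (0.26) and RUNX1T1 (0.20) did not pass, and without DMSO replicate 3 ASNS (0.090), DDIT3 (0.052), SEMA3D (0.11), PPP2R2B (0.053) and GALNT13 (0.069). Without HyT36 replicate 1 ASNS (0.094), HSPA5 (0.051), PPP2R2B (0.053), DAB2 (0.12), GALNT13 (0.16), LRATD2 (0.098) and MAGI2-AS3 (0.076) did not pass. The same held without replicate 2 for MAGI2-AS3 (0.20) and RUNX1T1 (0.10), and without replicate 3 for SEMA3D (0.059), GALNT13 (0.11), RUNX1T1 (0.15), LRATD2 (0.066) and MAGI2-AS3 (0.069). ESRP1 (0.062 to 0.099) and GATA3 (0.076 to 0.13) did not pass without DMSO replicate 1 or 3 or any of HyT36, nor GATA3 without DMSO 2. Camera no longer called the respiratory chain (0.058), TGF-beta (0.12), proteasome (0.095) and ribosomal protein (0.22) lists without HyT36 replicate 1, or the fibroblast (0.065) list without HyT36 replicate 3. Camera did not call the proteasome list without DMSO replicate 2 (0.058), or the fibroblast (0.062) and ribosomal protein (0.19) lists without DMSO replicate 3.

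**Figure D3:**
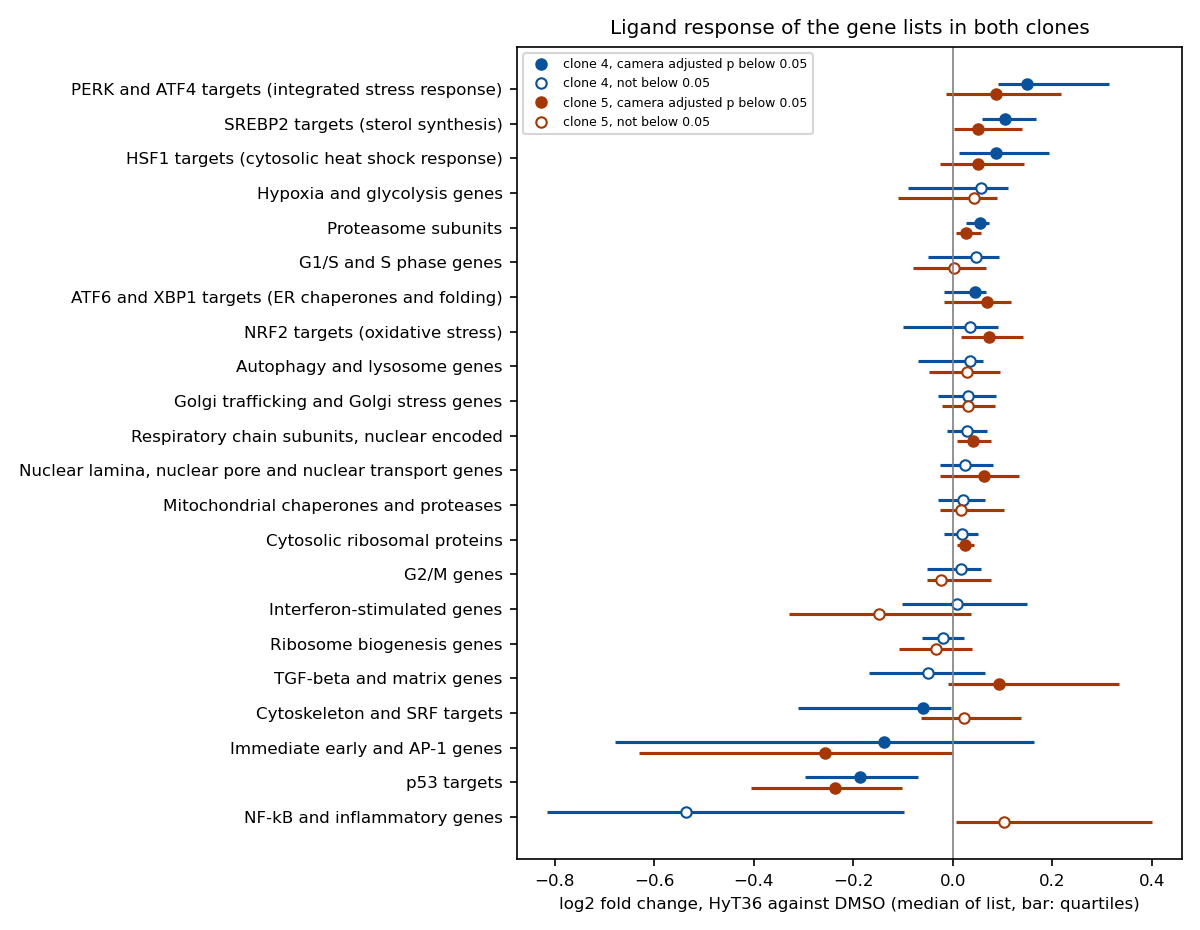
Median log2 fold change, HyT36 against DMSO, of the 22 lists of responses and cell functions in both clones, with bars from the lower to the upper quartile of their members and filled points for a camera adjusted p under 0.05 at the preset correlation. The PERK and ATF4 targets had medians of 0.15 in clone 4 and 0.09 in clone 5, and the p53 targets -0.19 and -0.24.

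The responses of both clones shared 413 genes that passed in the same direction, 125 rising and 288 falling, against 35.2 for independent lists of these sizes, and no control libraries were shared between them. Besides the stress genes above, KLF10, CCN2, CDKN1A, AEN and TNFRSF10B fell in both clones. Only 4 genes passed in opposite directions: OR2I1P, C1R, NUAK1 and TTC19, named after their values were seen. Over all genes called in both clones, those 4 included, the log2 fold changes correlated across genes with r = 0.88, which their choice by calls in both clones can make high. Over all 14892 tested genes r was -0.06, and genes are not independent replicates. This r is unweighted, so genes with few reads count as much as others. It also includes the epithelial markers, whose list had a median of 0.27 in clone 4 and -2.30 in clone 5. It therefore does not show that the responses disagree. The shared count fell to 241 without clone 4 HyT36 replicate 3, to 224 with the term for epithelial transcripts and to 16 against a fold of 1.2.

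**Figure D4:**
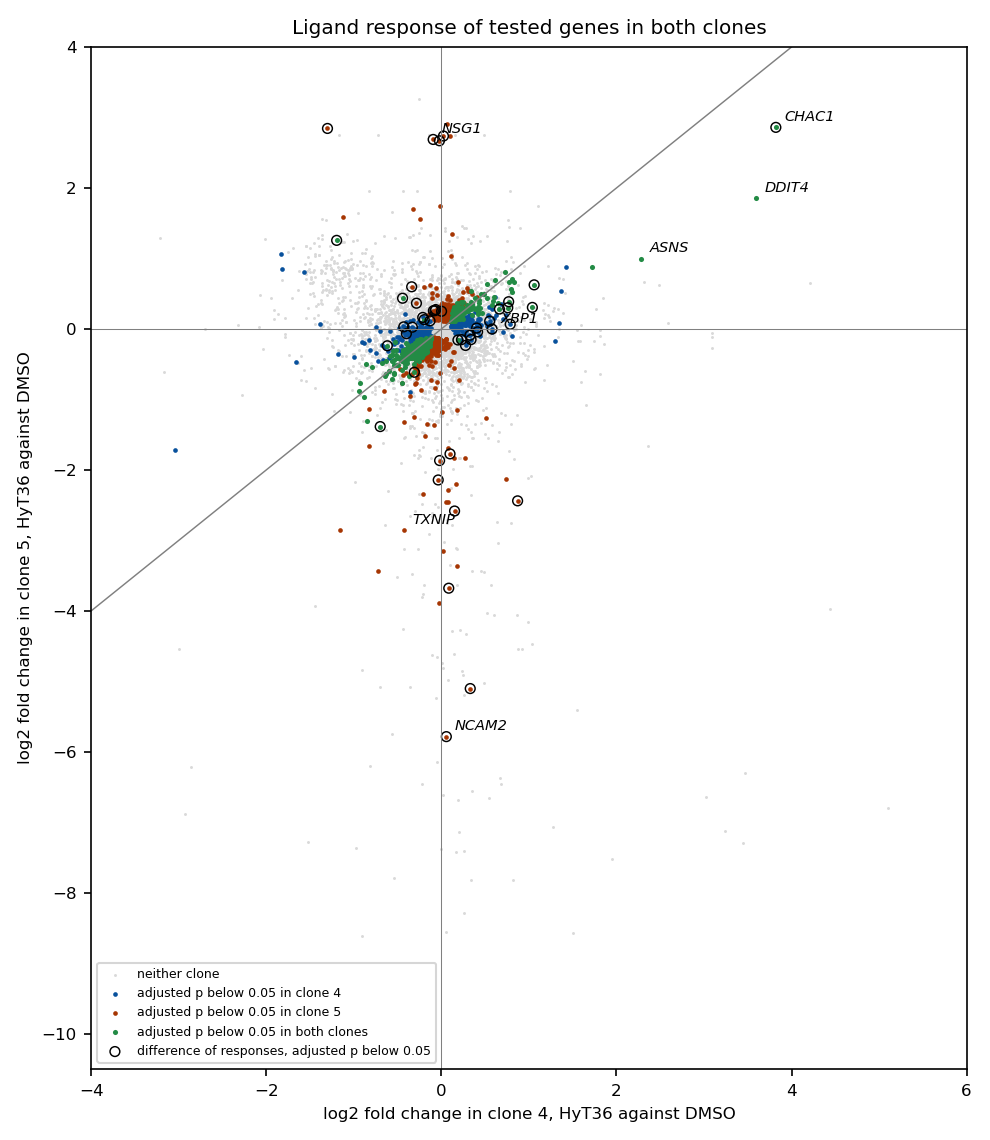
Log2 fold change with HyT36 in clone 4 against that in clone 5 for each of the 14892 tested genes, with the genes that passed in 1 clone, in both, and in the test of the difference marked. CHAC1 lies at 3.82 and 2.86, and XBP1 at 0.58 and -0.00.

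A test of the difference between the responses asked which genes the ligand changed more in one clone than in the other. It called 45 genes, 19 with a higher and 26 with a lower log2 fold change in clone 5, and stress genes were among the latter. XBP1, which rose in clone 4, differed by -0.58 ± 0.05 on the log2 scale (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 6.9e-09). The co-chaperone gene DNAJB1 differed by -0.46 ± 0.06 (adjusted p = 2.0e-05), HERPUD1 by -0.43 ± 0.07 (adjusted p = 0.0014) and CHAC1 by -0.96 ± 0.18 (adjusted p = 0.0060). STC2 differed by -0.38 ± 0.08, the growth factor gene VEGFA by -0.44 ± 0.10 and SESN2, an inhibitor of mTORC1 signalling, by -0.72 ± 0.13 (edgeR adjusted p = 0.021, 0.021 and 0.044). For DDIT4 (-1.73 ± 0.28, edgeR adjusted p = 0.054), ASNS (-1.29 ± 0.40, 0.25), DDIT3 (-0.83 ± 0.33, 0.45) and HSPA1B (-0.29 ± 0.08, 0.20) a difference was not shown. Nor was it by edgeR for BAG3 (-0.32 ± 0.10, 0.24), ATF3 (-0.11 ± 0.11, 0.88), HSPA5 (-0.05 ± 0.05, 0.86) and ATF4 (-0.00 ± 0.07, 1.0). At a mean log2 CPM of at least 1 the largest differences belonged to genes near the detection limit in clone 5: NSG1 (2.78 ± 0.55), PPP2R2B (2.69 ± 0.62), NCAM2, SEMA3D (-2.73 ± 0.60), NIBAN1 (-2.11 ± 0.38), NELL1 (-1.87 ± 0.42) and SH2D4A (-1.85 ± 0.39). The fitted sizes for PPP2R2B, NCAM2 and SEMA3D depend on the prior count, since 1 group of clone 5 had 3, 0 and 3 reads. The metalloproteinase gene MMP15 (0.94 ± 0.22), the complement gene C1R (0.88 ± 0.18) and the kinase gene SGK1 (0.65 ± 0.13) were the next higher ones within that limit.

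By list, 3 PERK and ATF4 targets (CHAC1, STC2 and SESN2) had a lower response in clone 5 (13 lower and 1 higher adjusted over the list alone). Together these targets responded less there (camera adjusted p = 4.4e-08, and adjusted p = 0.15 with an estimated correlation). Cytoskeleton and SRF targets, which fell in clone 4 and did not pass in clone 5 (camera adjusted p = 0.44), differed upward (camera adjusted p = 3.3e-07, and adjusted p = 0.21 with an estimated correlation), with 1 call, CCN1 at 0.38 ± 0.08 (2 adjusted over the list alone). SREBP2 and p53 targets differed downward as lists (camera adjusted p = 0.016 and 0.033, and adjusted p = 0.22 and 0.74 with an estimated correlation). Among p53 targets the 1 call was SESN2, which rose in clone 4 and is also a PERK and ATF4 target (2 adjusted over the list alone). A deeper fall of p53 targets in clone 5 is therefore not shown. For SREBP2 targets edgeR and limma-voom made 0 calls and DESeq2 1, with 1 higher and 5 lower at an unadjusted edgeR p under 0.05 (3 lower adjusted over the list alone). NF-kB genes, which did not pass in either clone (camera adjusted p = 0.076 and 0.33), differed upward (camera adjusted p = 0.0055, and adjusted p = 0.67 with an estimated correlation), with 0 of 15 called by edgeR, DESeq2 or limma-voom (0 adjusted over the list alone) and 1 at an unadjusted edgeR p under 0.05. The epithelial markers, whose libraries coincide with DMSO in clone 5, differed downward at a median of -2.83 (camera adjusted p = 2.9e-04, and adjusted p = 0.67 with an estimated correlation). Of these 10, 0 were called by edgeR or limma-voom, 1 by DESeq2 and 2 at an unadjusted edgeR p under 0.05 (1 lower adjusted over the list alone). With the term for epithelial transcripts 244 genes differed, 210 upward and 34 downward, so that the balance of direction turned. The epithelial markers turned direction (camera adjusted p = 9.7e-04) with that term, and STC2 (edgeR adjusted p = 0.40), VEGFA (0.10), CCN1 (0.057), PPP2R2B (0.056), SH2D4A (0.16) and MMP15 (0.086) did not pass.

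The count of 45 differing genes was 12 with limma-voom, 169 without a filter and 7 against a fold of 1.2. It was 140 without clone 4 DMSO replicate 1, 27 without clone 4 HyT36 replicate 2, and 25 and 29 without clone 5 HyT36 replicates 1 and 2. The calls of XBP1 and NCAM2 held in every fit and those of HERPUD1 and DNAJB1 in all but the fold threshold (edgeR adjusted p = 0.90 and 0.19). With limma-voom those of CHAC1 (0.16), SGK1 (0.067), C1R (0.082), STC2 (0.13), VEGFA (0.095), CCN1 (0.13), NSG1 (0.28), PPP2R2B (0.32), SEMA3D (0.28), NIBAN1 (0.28), NELL1 (0.33), SH2D4A (0.28) and MMP15 (0.28) were lost. In clone 5, leaving out DMSO replicate 1 ended the calls of NELL1 (0.54) and SH2D4A (0.12), and DMSO 2 those of STC2 (0.11), VEGFA (0.099) and PPP2R2B (0.13). Leaving out DMSO 3 ended those of STC2 (0.095), SESN2 (0.11), CCN1 (0.063), PPP2R2B (0.26), SEMA3D (0.33) and MMP15 (0.16). Leaving out HyT36 1 ended those of STC2 (0.087), VEGFA (0.11), SESN2 (0.19), CCN1 (0.054), PPP2R2B (0.29), SH2D4A (0.11), MMP15 (0.094) and C1R (0.052). Leaving out HyT36 2 ended those of STC2 (0.11), SESN2 (0.17), CCN1 (0.064), NSG1 (0.17), PPP2R2B (0.11), SEMA3D (0.12), NIBAN1 (0.062), NELL1 (0.18) and MMP15 (0.10). Without HyT36 3 of clone 5 SESN2 (0.15), SEMA3D (0.21), NIBAN1 (0.052), NELL1 (0.14), SH2D4A (0.059) and MMP15 (0.090) did not pass. In clone 4, leaving out DMSO 2 ended the calls of STC2 (0.063), PPP2R2B (0.067) and MMP15 (0.068), DMSO 3 those of STC2 (0.066), VEGFA (0.058), SESN2 (0.052) and PPP2R2B (0.052), and HyT36 1 those of SESN2 (0.12) and PPP2R2B (0.069). Without HyT36 2 of clone 4 STC2 (0.089), VEGFA (0.10), SESN2 (0.15), CCN1 (0.064), PPP2R2B (0.052), SH2D4A (0.053) and MMP15 (0.091) did not pass, and without HyT36 3 STC2 (0.055), SESN2 (0.12), SH2D4A (0.051) and MMP15 (0.11) did not. By camera the p53 targets were not called without clone 4 DMSO 1 (0.061), DMSO 3 (0.12) or HyT36 2 (0.25) or clone 5 DMSO 2 (0.21), HyT36 1 (0.090) or HyT36 3 (0.097). Camera did not call the SREBP2 targets without clone 4 or clone 5 DMSO 3 (0.087 and 0.14), and the NF-kB genes without clone 5 DMSO 3 (0.11).

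Without ligand, the clones differed in 55.5% of all genes tested. Clone 5 expressed SLFN11, a restrictor of stalled replication forks, at 72.7 ± 2.27 CPM against 0.164 ± 0.00647 CPM in clone 4 (SD, n = 3), and the kinase gene SYK at 96.8 ± 1.68 against 0.285 ± 0.137 CPM. Clone 4 expressed RELN, a secreted matrix glycoprotein gene, at 45.4 ± 0.660 CPM against 0.225 ± 0.0887 CPM in clone 5, and LIN28A, an inhibitor of let-7 processing, at 21.2 ± 1.47 against 0.0906 ± 0.0475 CPM. The edgeR quasi-likelihood test called 8259 genes, 4059 higher and 4200 lower in clone 5, and 1880 by more than 2-fold, 1082 up and 798 down. The log2 differences were 8.75 ± 0.15 for SLFN11 and 8.37 ± 0.11 for SYK (edgeR adjusted p = 1.7e-33 and 1.1e-39), and -7.60 ± 0.14 for RELN and -7.81 ± 0.19 for LIN28A (1.7e-35 and 2.5e-31). Also far higher in clone 5 were the transporter genes SLCO1B3 (7.57 ± 0.23) and SLC5A12 (7.36 ± 0.26), POF1B (6.83 ± 0.12), the immune receptor gene BTLA (6.66 ± 0.18), the mitotic checkpoint gene CHFR (6.59 ± 0.20) and PROM1 (6.47 ± 0.13). With few reads in clone 4, TRDN (562 reads against 1, ratio 539, counting interval 96.3 to 21321) and PDE4D (461 against 3, ratio 147, 50.1 to 717) were higher as well. Far lower were CYYR1 (-7.83 ± 0.19), NSG1 (-7.34 ± 0.29) and NEGR1 (-7.19 ± 0.29). With few reads in clone 5 these were joined by RUNX1T1 (699 reads in clone 4 against 1, ratio 729, 130 to 28836), and SEMA6D (424 against 1, ratio 442, 78.9 to 17507). The same held for the growth factor gene VEGFC (334 against 1, ratio 348, 62.1 to 13800), PPP2R2B (784 against 3, ratio 273, 92.9 to 1325) and ADPRH (298 against 1, ratio 311, 55.4 to 12317).

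Genes on the X chromosome were mostly higher in clone 5. Of 494 tested X-linked genes 419 were higher, 30 lower and 45 not called, with a median log2 difference of 0.91 (quartiles 0.68 and 1.22), while 3369 of 13439 autosomal genes were higher, 25.1%. The X-linked gene XIST was left out of this set, and its value is not reported here. The X-linked genes higher in clone 5 included EBP (0.93 ± 0.04) of sterol synthesis, the glycolytic enzyme gene PGK1 (0.86 ± 0.04), and the ribosomal protein gene RPS4X (0.90 ± 0.04). Others were the filamin gene FLNA (0.91 ± 0.03), the lysosomal enzyme gene GLA (0.85 ± 0.05) and the lysosomal membrane gene LAMP2 (1.00 ± 0.04).

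**Figure D5:**
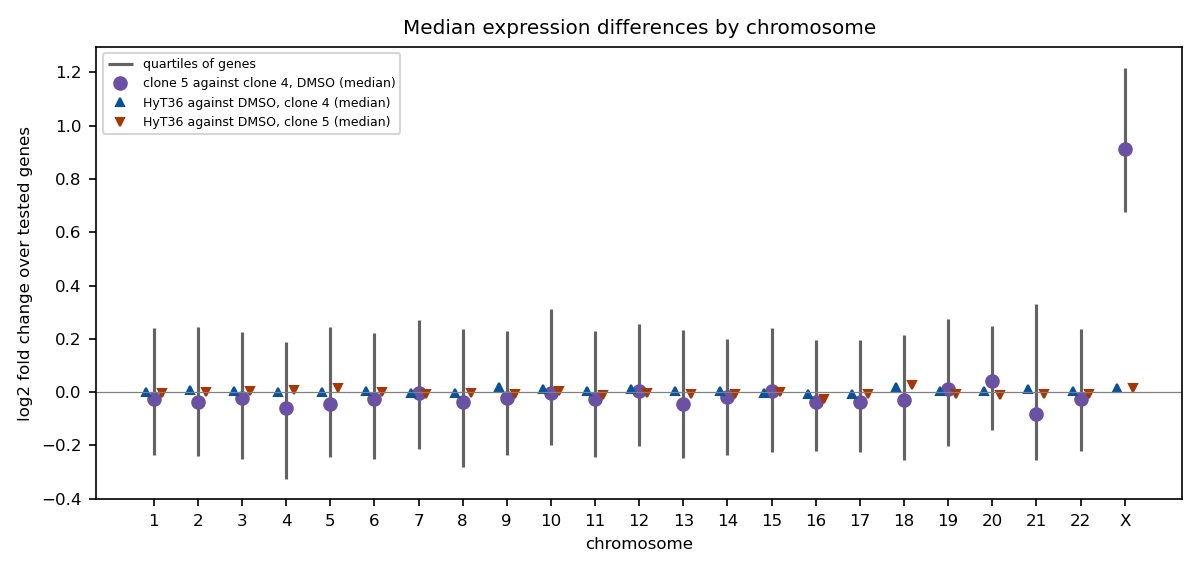
Median log2 difference between clone 5 and clone 4 without ligand over the tested genes of each chromosome (XIST left out), with the quartiles as lines, and as triangles the median log2 fold change with HyT36 in each clone. For clone 5 against clone 4 the X chromosome lies at 0.91 and the autosomes lie between -0.08 and 0.04.

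Several stress genes also started from different levels. Without ligand CHAC1 was lower in clone 5 by -1.94 ± 0.14 on the log2 scale, HMOX1, which degrades heme, by -1.50 ± 0.11 and the AP-1 gene JUN by -1.88 ± 0.15 (edgeR adjusted p = 6.1e-15, 3.6e-15 and 1.9e-13). CCN1 differed by -2.92 ± 0.05, ATF4 by -0.42 ± 0.05 and HSPA1A by -0.54 ± 0.06 (edgeR adjusted p = 1.7e-35, 1.8e-07 and 9.1e-11), whereas BAG3 (0.52 ± 0.07) and SDF2L1 (0.41 ± 0.05) were higher. XBP1 (-0.02 ± 0.04), HERPUD1 (-0.06 ± 0.05), DNAJB1 (-0.01 ± 0.04), DDIT3 (-0.03 ± 0.25) and ASNS (-0.03 ± 0.32) did not pass.

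As lists, 10 were lower in clone 5 without ligand by camera at the preset correlation, and 0 were called with an estimated one. Of 10 splits of these libraries, 4, the real one included, called as many lists. PERK and ATF4 targets (camera adjusted p = 3.1e-05, and adjusted p = 0.35 with an estimated correlation) had 26 lower and 4 higher members among 44 (27 and 4 adjusted over the list alone). Among the lower ones were the mitochondrial one-carbon and gluconeogenic genes SHMT2 (-0.82 ± 0.04) and PCK2 (-1.23 ± 0.07) and the serine synthesis gene PSAT1 (-0.61 ± 0.04). Ribosomal proteins (camera adjusted p = 1.8e-04, and adjusted p = 0.89 with an estimated correlation) had 42 lower and 6 higher among 72 (42 and 6 adjusted over the list alone), such as RPL7A (-0.49 ± 0.03) and RPS23 (-0.51 ± 0.04). G2/M genes (camera adjusted p = 0.0045, and adjusted p = 0.45 with an estimated correlation) had 18 lower and 1 higher among 30 (18 and 2 adjusted over the list alone), such as NDC80 (-0.78 ± 0.05) and CDC20 (-0.40 ± 0.04). Nuclear lamina, pore and transport genes (camera adjusted p = 0.0045, and adjusted p = 0.45 with an estimated correlation) had 18 lower and 3 higher among 28 (19 and 3 adjusted over the list alone), such as LMNA (-0.53 ± 0.04). HSF1 targets (camera adjusted p = 0.012, and adjusted p = 0.45 with an estimated correlation) had 17 lower and 2 higher among 31, the same adjusted over the list alone, such as SERPINH1 (-0.61 ± 0.04) and HSP90AB1 (-0.53 ± 0.04). Mitochondrial chaperones and proteases (camera adjusted p = 0.018, and adjusted p = 0.51 with an estimated correlation) had 11 lower and 1 higher among 18 (13 and 1 adjusted over the list alone), such as TRAP1 (-0.36 ± 0.04).

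Hypoxia and glycolysis genes were lower too (camera adjusted p = 0.020, and adjusted p = 0.35 with an estimated correlation), 13 lower and 2 higher among 24 (the same adjusted over the list alone). Among the lower were the glucose transporter gene SLC2A3 (-2.53 ± 0.27) and TPI1 (-0.60 ± 0.04). Cytoskeleton and SRF targets (camera adjusted p = 0.020, and adjusted p = 0.51 with an estimated correlation) had 14 lower and 5 higher among 25, the same adjusted over the list alone, such as TPM2 (-1.68 ± 0.07) and TUBB6 (-0.80 ± 0.04). SREBP2 targets (camera adjusted p = 0.032, and adjusted p = 0.35 with an estimated correlation) had 14 lower and 4 higher among 29, the same adjusted over the list alone, such as TM7SF2 (-1.03 ± 0.07). Immediate early genes (camera adjusted p = 0.038, and adjusted p = 0.39 with an estimated correlation) had 18 lower and 3 higher among 30, the same adjusted over the list alone, with KLF4 (1.24 ± 0.05) among the latter. The epithelial transcripts were above 50 CPM in all 3 clone 5 libraries with DMSO and in 1 of 3 of clone 4, and the epithelial markers did not pass (camera adjusted p = 0.44). With the term for these transcripts the SREBP2 targets (camera adjusted p = 0.060) and mitochondrial chaperones (0.064) were not called, and in only the libraries with many of them, 1 of which is of clone 4 without ligand, these (0.055 and 0.11) and the ribosomal proteins (0.11) were not. Against a fold of 1.2 the count of 8259 genes was 3986. By camera the SREBP2 targets and the immediate early genes were not called with the stricter filter (adjusted p = 0.056 each), nor the former without clone 4 DMSO replicate 2 (0.051) or the latter without clone 5 DMSO replicate 3 (0.085).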

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

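The tests of the epithelial transcripts, of their effect on the stress genes and of the genes near the detection limit were chosen after the results had been seen, and the other splits of the samples and the test of library size were planned.

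The ligand response differed between the clones in 45 genes by the edgeR test of the difference and in 6 lists by camera, and this difference between groups is what drew attention to each value here. With an estimated correlation 0 lists were called (lowest adjusted p = 0.15). The median differences (log2, clone 5 minus clone 4) were -0.084 for PERK and ATF4 targets, -0.048 for SREBP2 targets, -0.062 for p53 targets, 0.58 for NF-kB genes, 0.11 for cytoskeleton and SRF targets and -2.83 for epithelial markers. With a higher log2 fold change in clone 5, NSG1 differed by 2.78, PPP2R2B by 2.69, MMP15 by 0.94, C1R by 0.88 and SGK1 by 0.65. With a lower one, fitted differences were -5.84 for NCAM2, which had 0 reads in clone 5 with HyT36, -2.73 for SEMA3D, -2.11 for NIBAN1, -1.87 for NELL1, -1.85 for SH2D4A, -0.96 for CHAC1, -0.58 for XBP1, -0.46 for DNAJB1 and -0.43 for HERPUD1. Of 50 splits of the libraries within both clones, drawn from 200, 4 gave as many differing genes as the real one, itself included (45 against a highest other of 135), so chance is not excluded by this count. The 3 others, with 135, 77 and 69 genes, keep the real ligand groups of 1 clone and so hold its ligand response. They are thus not splits without an effect, and the highest count of a split that keeps neither clone's groups, looked up after these values were seen, was 9. For the lists chance is not excluded either, as 39 of the 50 gave as many (6 against a highest other of 17 and a median of 8 over the others).

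The stronger response of some stress genes in clone 4 is the first pattern weighed. Over the 6 members of stress lists called lower in clone 5 (XBP1, DNAJB1, HERPUD1, CHAC1, STC2 and SESN2) the differences ran from -0.96 to -0.38, with a median of -0.52 that their choice by calls makes large, while the whole lists of ATF6 and XBP1 targets (median 0.012, camera adjusted p = 0.96) and of HSF1 targets (-0.023, camera adjusted p = 0.090) were not shown to differ. After every library was thinned to 22853946 gene counts the median was -0.52, and 4 of the 6 were called, with SESN2 and STC2 at edgeR adjusted p = 0.060 and 0.051 at almost the same sizes. Thinning leaves expected CPM ratios unchanged, so the median could hardly have moved. It shows only that those 4 calls hold at equal library sizes. With a term for the epithelial transcripts the median difference was -0.54 and 5 were called, with STC2 at -0.22, which argues against those transcripts as the whole cause, although in clone 5 the term coincides with the ligand and takes its size from clone 4. A biological difference between the clones may remain, as a hypothesis found and tested on the same data, and the tagged protein, the levels without ligand and clonal variation cannot be separated with 1 clone of each kind.

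The epithelial transcripts in 6 libraries are the second. A ligand effect is argued against, since the highest clone 4 library with HyT36 held 15.5 times the epithelial-list CPM of the lowest with DMSO, and so is a swap of labels, since all 12 libraries had their guide and CHAC1 level on the side of their labels. RNA or reads of another cell type or library may account for them: 7 members of a breast luminal list had neither been seen nor served to define the libraries, and 100% of the 7 were higher in all 3 such clone 4 libraries than in the other 3, where chance gives 5% per gene and 3 of the 7 are also expressed. Of the whole list 19 of 19 measured members were, with KRT8 up to 126 CPM, KRT19 up to 70.5 and TFF1 up to 21.4. Whether cells, free RNA or reads of other libraries brought them is open, and in clone 5 they cannot be parted from the ligand.

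Genes of clone 4 near the detection limit in clone 5 are the third, with no biological explanation tested, and reads of clone 4 libraries may account for falls of the lowest of them. There were 7 genes at 20 CPM or more in clone 4 and under 1% of that on average over both clone 5 groups. With DMSO alone HAPLN3 and SEMA3D were at 1.28% and 1.26%. In clone 5 the 7 went from 208 reads with DMSO to 102 with HyT36, and the HDAC2 guide of clone 4 fell there by 1.52 on the log2 scale. The median log2 ratio was -0.96 over the 7 and -0.57 over the 5 whose fall had not been seen, whose reads went from 147 to 89 (ratio 0.665, counting interval 0.506 to 0.872). The bound of -0.5 was set after these values were known, so this test could hardly have come out otherwise. NSG1, PPP2R2B and RUNX1T1, chosen because they rose, together had 7.28 times the CPM in clone 5 with HyT36, which restates their rise, but their 0.356, 0.269 and 0.128 CPM there against 8.46, 10.5 and 9.97 in clone 4 with HyT36 argue against such reads as their source, since the clone 4 guide had 0.200% of its clone 4 level there and was lower than with DMSO. The falls of NCAM2, NIBAN1 and SH2D4A are too large for reads of clone 4 libraries, since in clone 5 with DMSO they had 0.271, 0.964 and 1.16 CPM against 4.95, 10.4 and 4.26 in clone 4, while the guide had 0.574%. The source that brought the epithelial transcripts to the clone 5 libraries with DMSO was not tested as a cause of these falls.

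Of a liver list 0 of 20 members were higher in all 3 clone 4 libraries with epithelial transcripts than in the other 3. Clone 4 DMSO replicate 1 stood apart, with 845 CPM of the liver list against 66.5 to 312 in the other 11 libraries. Without the members at a mean of at least 1 CPM in the libraries with few epithelial transcripts, it had 6.23 against 0.631 to 2.43. Its counts also differed most from those of its group, at a chi-square per degree of freedom of 8.43 and 7.23 against 2.71 between the other 2. Liver transcripts were found in every library, and their sums parted DMSO from HyT36 in both clones, in opposite directions. Clone 4 had 845, 205 and 197 CPM with DMSO and 156, 167 and 166 CPM with HyT36. Clone 5 had 221, 227 and 66.5 CPM with DMSO and 312, 303 and 282 CPM with HyT36. The cause was not tested.

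Guide features were left out of the gene tests, and their reads drew attention to 3 of them. Reads in the other clone were 49 of the IGF1R guide in clone 4 and 66 of the HDAC2 guide in clone 5. The LRIG1 guide, a further guide of clone 5, had 712 reads there against 0 in clone 4.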

How the results depend on the processing

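The 4 fits that treat the epithelial transcripts were chosen after the data had been seen, and all other alternatives were planned. Over all alternatives, calls and directions of the named genes were the same in 11861 cases, weaker in 654 and stronger in 180, with 0 reversed; for lists the numbers were 1991, 81, 85 and 18. Of the counts, 156 stayed within 1.5 times the value given in the report and 31 did not.

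Against a fold of 1.2 the counts were 52 genes for clone 4, 37 for clone 5, 7 for the difference, 3986 for the clones without ligand and 16 shared genes, as the test asks for larger changes. Limma-voom called 12 differing genes, and no filter on low counts gave 169. With an estimated correlation camera called 2, 0, 0 and 0 lists in clone 4, clone 5, the difference and the clones without ligand, with 6, 8, 3 and 3 at an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 8 lists in clone 5 and 1 in the difference. The term for the epithelial libraries gave 776 genes in clone 5, 244 differing and 224 shared genes, 16 lists in clone 4 and 15 for the difference. In clone 5 that term coincides with the ligand, so its size comes from clone 4. Removal of the genes higher in those libraries left 823 genes in clone 4, against 830. The 774 removed genes were chosen by differences within the clone 4 groups, which makes them hard to call there. Only 13 falls and 7 rises of clone 4 were among them, so this count could hardly change. Only the libraries with few epithelial transcripts gave 287 genes in clone 4, where HyT36 has 1 library, and only those with many gave 18 lists there, where DMSO has 1. A lone library is assumed to vary like the other groups. The cause was not tested for the other changes.

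With 1 library left out the counts ranged from 409 to 851 genes in clone 4, 755 to 1618 in clone 5, 25 to 140 for the difference, 7556 to 8340 without ligand and 241 to 435 shared. Lists ranged from 8 to 13, 10 to 16, 4 to 11 and 9 to 11 in the same order. Clone 4 had 545, 532 and 409 genes without its HyT36 replicate 1, 2 and 3 and 13 lists without its DMSO replicate 2, and clone 5 had 755 genes without its DMSO replicate 1. The difference had 140 genes without clone 4 DMSO replicate 1, 27 without clone 4 HyT36 replicate 2, 25 and 29 without clone 5 HyT36 replicates 1 and 2, and 11 lists without clone 4 DMSO replicate 2. The shared count was 241 without clone 4 HyT36 replicate 3.

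All 18 reversed lists came from fits that treat the epithelial transcripts. With the term, adjusted p by camera for the turned direction were 0.0147, 2.0e-09 and 3.7e-12 for interferon-stimulated genes (clone 4, clone 5, difference) and 0.00105, 0.0419, 9.7e-04 and 0.0312 for epithelial markers (the same and the clones without ligand). They were 0.351 for proteasome subunits (clone 5), 0.215 and 0.00128 for ribosomal proteins and 0.0108 and 0.00893 for mitochondrially encoded RNA (clone 5, difference). With only the high-epithelial libraries, where clone 4 without ligand is replicate 1 alone, they were, for clone 4 and for the clones without ligand, 0.00181 and 0.0332 for interferon-stimulated genes, 7.5e-08 and 0.0156 for mitochondrially encoded RNA, and 8.6e-04 and 0.0185 for epithelial markers. The cause was not tested.

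The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries from their group means correlated between -0.54 and 0.16. This does not exclude pairing, since in clone 4 the epithelial transcripts lay in DMSO replicate 1 but in HyT36 replicates 2 and 3. With the replicate block the counts were 758, 1136, 60 and 8093 genes, 373 shared genes, and 9, 14, 7 and 10 lists. Among called genes of clone 5, 40.9% rose, against 48.8% with size factors and 50.9% with DESeq2. Depth limits genes near the detection limit most, where 1 to 3 reads in a group leave intervals such as 2.05 to 36.7 for PPP2R2B.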

Other observations

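The test of X-linked genes was chosen after the result had been seen, and the test of autosomes and the other splits of the samples were planned. Genes named here that were not named before were chosen after their values were seen.

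Some genes fell with HyT36 in both clones without their list passing. ARRDC4, an arrestin family gene regulated by glucose, fell by 0.85 in clone 4 on the log2 scale (edgeR adjusted p = 5.3e-07) and fell in clone 5 too (7.5e-13). GRPEL1, a co-chaperone of mitochondrial protein import, fell by 0.27 and 0.33, and RRS1, a ribosome assembly gene, by 0.22 and 0.31. The secretory pathway genes MCFD2 and TMED9 fell by 0.17 and 0.18 in clone 4 and by 0.26 and 0.18 in clone 5. The host gene of small nucleolar RNAs SNHG12 fell by 0.34 and 0.41, and the transcription factor gene GATA2 by 0.40 and 0.29. In clone 5, 7 of 33 ribosome biogenesis genes fell and 4 rose (9 and 6 adjusted over the list alone), the falls including NOP56 (-0.21), NOP2 (-0.21) and WDR43 (-0.19), and the list did not pass (camera adjusted p = 0.26). In clone 4, the angiogenic factor gene VEGFA rose by 0.55 while ADM, a vasodilator peptide gene, fell by 0.61 and the glycolytic regulator gene PFKFB3 by 0.29, and hypoxia and glycolysis genes as a list did not pass (camera adjusted p = 0.14).

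Lineage and matrix genes differed between the clones without ligand in both directions. Clone 5 was lower in the kidney genes CDH6 (-1.14 ± 0.04), LRP2 (-3.53 ± 0.52) and LHX1 (-0.57 ± 0.08), in the neurofilament gene INA (-1.25 ± 0.17), and in the matrix genes LOX (-3.23 ± 0.11) and TGFB2 (-3.44 ± 0.30). It was higher in GAP43 (1.74 ± 0.18), a growth cone gene, and in TIMP1 (1.34 ± 0.06), an inhibitor of metalloproteinases (± SE, edgeR adjusted p at most 2.2e-07 for these 8). The kidney, neural and TGF-beta lists did not pass (camera adjusted p = 0.15, 0.96 and 0.58).

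A hypothesis is that clone 5 has more transcribed copies of the X chromosome than clone 4. Over 487 tested X-linked genes, leaving out XIST and 7 in which the difference was noticed, the median log2 difference was 0.91 (quartiles 0.67 and 1.22), and 0 of 1000 random gene sets of that size had one as large (highest 0.06). The 10 blocks of neighbouring X genes, 9 of 50 genes and 1 of 44, had medians of 0.82 or more, and 256 autosomal blocks -0.24 to 0.29. With HyT36 in both clones the X median was 0.93. The bounds for this test were set when the median was already known, so it was found and tested on the same data, and more copies and a loss of silencing of a copy may each give it. Of the higher genes placed on an autosome or the X chromosome 11.1% were X-linked.

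Whole-autosome copy number is argued against as a source of the other differences between the clones, since autosome medians lay between -0.08 and 0.04. Their SD was 0.0260, which 27 of 1000 shuffles of genes over chromosomes reached (highest 0.0342), as 26 of 1000 did for the clone 5 ligand response. The SD over the autosomal blocks, 0.0742, lay above all 1000 shuffles (highest 0.0635), so regional differences are open.

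The 6 libraries of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. The real split gave 830 genes in clone 4 (highest other 174), 1219 in clone 5 (0) and 8259 without ligand (0), each reached by 1 of the 10, itself. The split with 174 follows the epithelial transcripts and called 14 lists. For lists the real values were 8 (reached by 7 of 10, highest other 15), 14 (1 of 10, highest other 11) and 10 (4 of 10, highest other 16), so list counts did not stand out in clone 4 or without ligand. The other splits called a median of 10, 7 and 5 lists, although their median count of genes was 0 in each comparison. Camera at the preset correlation thus often called lists under labels other than the real ones, and its calls alone do not show a response. For genes shared by both clones, 1 of 50 drawn splits, the real one, gave as many as 413 (highest other 0). That share is under 0.05, but every other split of clone 5 alone called 0 genes, so a shared count of 0 was nearly fixed for the others. This test therefore adds little to the counts of each clone. It does not show that the clones share more than independent responses would.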
